A study of Mus musculus with 4 samples.

How the data were processed

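The study measured how often each guide RNA occurred in pooled CRISPR activation cultures. In such a screen each cell carries a guide that directs an activating complex, here the SunTag system, to the promoter of a gene, and guides are counted from genomic DNA. The cells, called cSAM, are mouse myeloid leukaemia cells transformed by mutant SETBP1 together with mutant ASXL1 and grown with interleukin-3. Per the labels' protocols, cells with the library were grown for 7 days with the vehicle DMSO, with 50 nM DAC (decitabine, a deoxycytidine analogue that inhibits DNA methylation) or with 500 nM SAHA (vorinostat, an inhibitor of histone deacetylases). Also per the labels' protocols, genomic DNA was cut with SbfI, size-selected on a gel and amplified by PCR with indexed primers.

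The authors deposited a table of raw read counts per guide, not normalized, with a column for each of the 4 libraries, and per the file headers each column is replicate 1. The guide counter, its version and the genome build behind the guide positions are not given in the sources used here, so no coordinates are printed. Groups came from the sample titles: day 0, day 7 DMSO, day 7 DAC and day 7 SAHA, with 1 library each. The day 0 sample also carries the treatment label DMSO, and its title was followed. The table listed 214210 guides, of which 108083 had a read in at least 1 library and 106127 had none. Non-targeting guides, which match no gene, made up 4340 of the listed guides and 2164 of those with a read. The guides named 19939 genes. Of these names 18652 were current symbols in the RefSeq gene table of assembly GRCm38.p6, 1167 matched a unique synonym in it and 120 matched neither. Gene names are printed as the file gives them, and that RefSeq table was used only for names and for which genes lie on the same chromosome.

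Totals were 75738480 reads at day 0, 53787983 in day 7 DMSO, 61767140 in day 7 DAC and 53895658 in day 7 SAHA. For non-targeting guides the median counting SD of a log2 ratio was 0.10 for DAC against DMSO, 0.13 for SAHA against DMSO, 0.21 for DMSO against day 0 and 0.14 for DAC against SAHA. The observed SD over non-targeting guides was 2.15, 2.62, 2.80 and 3.02 in the same order, so counting error was a small part of the spread between guides. PCR reads without molecular identifiers are not independent molecules. Every interval given for a share is a binomial interval over guides only, and covers neither the counting error of reads nor the spread between cultures.

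Counts were scaled to the geometric mean of the library totals. Guides with a mean scaled count of at least 20 over the 4 libraries were kept, which left 102183 guides, 2084 of them non-targeting. For each guide the log2 ratio of scaled counts was taken with a pseudocount of 1 and centred on the median non-targeting guide. It was divided by the SD of non-targeting guides of like count, in 10 bins of the mean count of both compared libraries. The score of a gene was the sum of these values over its guides divided by the square root of their number, for the 19802 genes with at least 3 guides. Its two-sided p came from 1000000 random draws of as many non-targeting guides, so the smallest p is 2e-06. The p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. This guide-set resampling test compares 2 libraries with each other. With 1 library per group it has no replicate check, it does not measure the spread between cultures, and it says nothing of how a second culture would behave. The value given for a gene is the mean log2 ratio over its guides with the SE over guides, and a guide at 0 reads makes that value depend on the pseudocount. Sets of 5 non-targeting guides do not centre on 0, and their means and middle 95% are given beside each comparison.

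The test was checked on simulated libraries built from the real counts, with the spread of non-targeting guides and 200 changed genes per comparison, 50 for each size and direction. The changed genes had at least 5 guides past the count minimum, and all guides of a gene were shifted alike. Recovery may be lower for genes with fewer guides or with guides of unequal strength. Of genes raised by 4 on the log2 scale the test recovered 74.0% for DAC against DMSO, 52.0% for SAHA against DMSO, 8.0% for DMSO against day 0 and 10.0% for DAC against SAHA. Of genes lowered by 4 it recovered 26.0%, 22.0%, 16.0% and 4.0% in the same order. Of genes raised by 2 it recovered 8.0% for DAC against DMSO and 0.0% in each of the other 3 comparisons, and of genes lowered by 2 it recovered 2.0% for SAHA against DMSO and 0.0% in the other 3. It called 4 of 19617 unchanged genes for DAC against DMSO, 5 of 19616 for SAHA against DMSO, 2 of 19711 for DMSO against day 0 and 1 of 19672 for DAC against SAHA. In 20 random halvings of the real non-targeting guides, with 1 part as null and sets of 5 from the other part tested as genes, 5.1%, 5.8%, 5.3% and 5.2% of 4160 sets had an unadjusted p under 0.05, and 3, 3, 2 and 2 sets passed the adjusted threshold. Adjustment was made within each halving of 208 sets, where any call is false. These calls are therefore to be set against 20 halvings and not against 4160 sets. The threshold of 0.05 may thus be lenient for genes close to it.

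Before the data were examined, 32 gene lists, the tests, 17 kinds of alternative and the rule for named genes were fixed. The rule took, per comparison and direction, the 8 genes of largest mean ratio among those past the threshold with at least 75% of guides of 1 sign, or the 3 genes of smallest p where none passed. It added up to 4 passing members of each list and a few drug-target and tumour genes whatever their result. Genes named outside it, among them the members that passed only over their own list, were chosen after their values were seen. A list's median was set against 10000 random lists of the same size matched on count, which describes these libraries and is not a test across cultures. With 32 lists in 4 comparisons, some medians lie beyond the random range by chance. Adjustment over a list alone was made within each list and comparison, so across them some of those calls can arise by chance too. The bins of like count were defined on the mean of both compared libraries after the count distributions had been looked at, and 4 further alternatives were chosen after seeing the data. Guides of other genes within 1000 bp of a named gene's guides were looked up from the positions in the file. Scaling factors for 2 alternatives came from edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, and no count model was fitted, since there are no replicates. All else used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Guide sequences, transcript levels of the activated genes and cell numbers were not analysed here.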

Results

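Guide counts were obtained from 4 libraries of mouse cSAM leukaemia cells that carried a genome-wide CRISPR activation library. They comprised 1 library from day 0 and 1 library each from day 7 cultures with DMSO, 50 nM DAC or 500 nM SAHA. The screen was designed to find genes whose activation makes the cells more sensitive or more resistant to DAC and to SAHA. Guides of a gene that become rarer with a drug than with DMSO are read as activation going with a smaller share of cells. Guides that become more frequent are read as the opposite. A single guide does not mark a gene here. Non-targeting guides themselves varied with an SD of 2.15 for DAC and 2.62 for SAHA against DMSO. No group had a replicate.

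Library totals ranged from 53787983 to 75738480 reads. The share of the 108083 detected guides without a read was 1.08% at day 0, 2.35% in DMSO, 10.49% in DAC and 14.9% in SAHA. Among non-targeting guides it was 1.02%, 1.02%, 8.04% and 12.66% in the same order. Counts were most uneven in the SAHA library, with a Gini coefficient of 0.757, against 0.599 in DAC, 0.444 in DMSO and 0.708 at day 0. The most abundant guide of the SAHA library targeted Cacna2d2 and had 174023 reads, and that of the DAC library targeted Psmd9 and had 76724. At day 0 the guides formed 2 separate classes of count, with 1.9% of guides within 2-fold of 200 reads. The class with at least 200 reads held 38.5% of targeting guides (95% Wilson interval 38.2 to 38.8) and 37.9% of non-targeting guides (35.9 to 40.0).

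**Figure D1:**
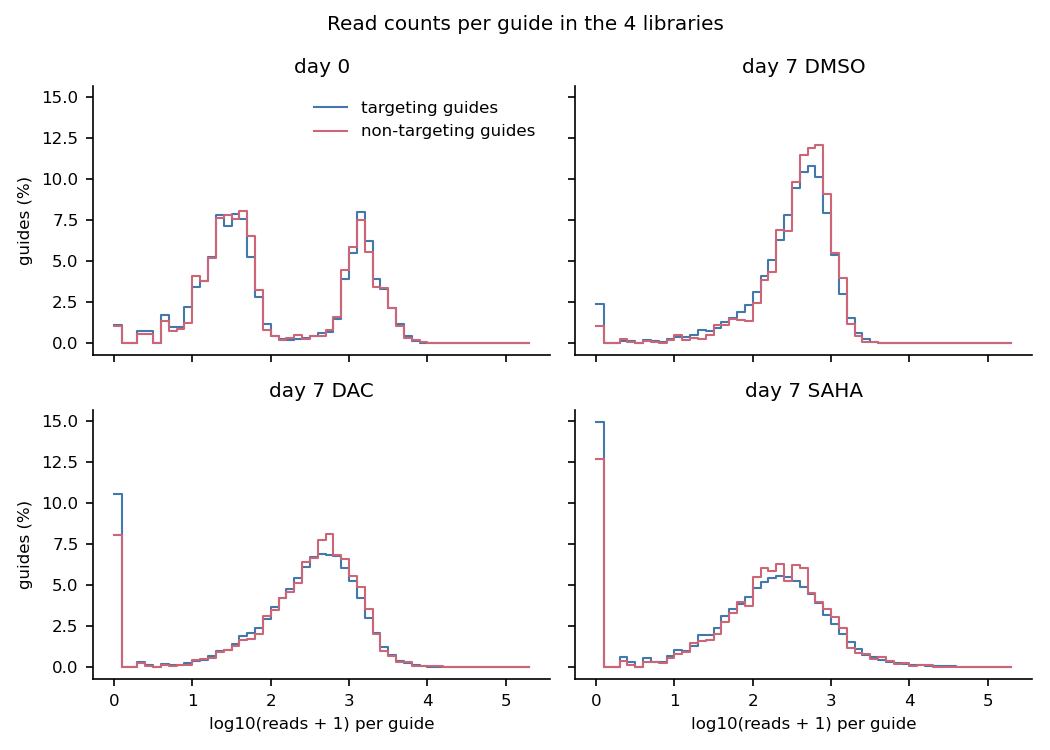
Histograms of reads per guide, as log10(reads + 1) on the x axis and percent of guides on the y axis, for targeting and non-targeting guides in each of the 4 libraries. Day 0 has 2 peaks, and the share of guides at 0 reads reaches 10.49% in DAC and 14.9% in SAHA.

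With DAC compared with DMSO, guides of 1 gene fell and passed the test. It was Dctpp1, the pyrophosphatase that hydrolyses dCTP and related deoxycytidine triphosphates, at a mean log2 ratio of -6.00 ± 2.25 (SE over 5 guides, 4 of them below 0; guide-set resampling test, adjusted p = 0.0396). Its guides had 4310 reads in DMSO and 235 in DAC, and 2 of the 5 had 0 reads in DAC. Guides of Dck, the kinase that phosphorylates decitabine in its activation, were at -5.45 ± 1.08 with 5 of 5 below 0 and 118 reads in DAC against 1583 in DMSO, but did not pass over all genes (adjusted p = 0.827). No gene passed in the higher direction, where 490 genes had an unadjusted p under 0.05, and the rank-sum of guides gave 0 as well. On the lower side 507 genes had an unadjusted p under 0.05, and chance gives 990 over both sides.

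The list of carriers and kinases that take up and phosphorylate nucleosides had 13 measured members, of which 0 passed over all genes and 4 were lower when adjusted over the list alone. These were Dck, the equilibrative nucleoside carriers Slc29a1 at -3.31 ± 1.13 over 10 guides and Slc29a2 at -3.81 ± 1.07 over 5 guides, and the thymidine kinase Tk1 at -3.47 ± 1.98 over 4 guides. The list's median of -1.12 lay at percentile 0.9 of random lists, whose middle 95% ran from -0.92 to 0.31. It lay at percentile 14.2 with a guide count minimum of 100 and at 13.8 with the guide median. Of 11 enzymes that break down cytidine analogues or their phosphates, 1 passed over all genes, Dctpp1. Over that list alone Nt5c, a cytosolic nucleotidase of deoxyribonucleotides, also passed, on the higher side, at 2.37 ± 0.72 over 5 guides. The deaminase Cda was at -2.77 ± 2.27 over 5 guides and the dNTP triphosphohydrolase Samhd1 at 1.58 ± 0.75 over 3 guides, and neither passed (adjusted p = 0.96 for each, guide-set resampling test).

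Dnmt1, the maintenance DNA methyltransferase that DAC traps, was at 1.91 ± 1.03 with 4 of 4 guides above 0 and did not pass (adjusted p = 0.96, guide-set resampling test), and it was at -2.32 with day 0 as the reference library. Ratios to day 0 carry the 2 classes of day 0 count and span the culture as well as the drug, so they are another contrast. In the DNA methylation list 0 of 13 members passed over all genes and 0 when adjusted over the list alone. Of 17 p53 pathway genes 0 passed over all genes. Adjusted over the list alone, 2 did, Mdm2, the ubiquitin ligase of p53, at 2.59 ± 0.71 over 4 guides and Btg2 at 2.07 ± 0.40 over 5 guides. Mitosis is the process that the series title names. None of the 28 spindle checkpoint and kinetochore genes, 18 anaphase-promoting complex genes, 10 mitotic entry genes or 16 cohesin and separase genes passed, over all genes or adjusted over the list alone. The medians of these lists lay at percentiles 18.2, 26.9, 69.2 and 96.3 of random lists. The genes of smallest p on the higher side were Dnph1, a hydrolase of deoxynucleoside monophosphates, at 2.38 ± 0.84, Mob1b, an adaptor of the Hippo kinases, at 2.03 ± 0.57 and Rimbp3 at 1.85 ± 0.62, and none passed (adjusted p = 0.304 for each, guide-set resampling test). Sets of 5 non-targeting guides had a mean of -0.37 with a middle 95% from -2.55 to 1.20. The call of Dctpp1 was lost with the rank-sum of guides, with a single SD for all guides and with day 0 as the reference library, where its value was -6.00, -6.00 and -5.80.

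**Figure D2:**
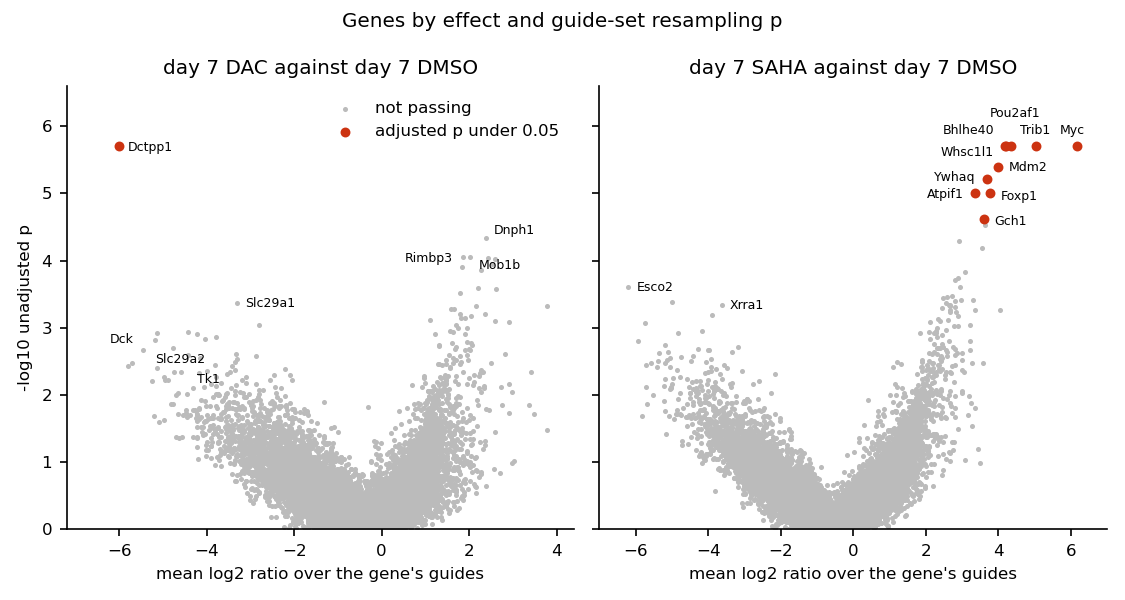
Mean log2 ratio over a gene's guides (x axis) against -log10 of the unadjusted p of the guide-set resampling test (y axis) for 19802 genes, with DAC on the left and SAHA on the right, each against DMSO. Dctpp1 passes at -6.00 with DAC, and 10 genes pass with SAHA, the highest of them Myc at 6.16.

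With SAHA compared with DMSO, guides of 10 genes rose and passed the test, and 0 genes passed on the lower side. The highest was Myc, the transcription factor of growth, at a mean log2 ratio of 6.16 ± 1.05 (SE over 5 guides, 5 of them above 0; guide-set resampling test, adjusted p = 0.00792). Its guides had 6370 reads in DMSO and 292608 in SAHA. Next came Trib1, a pseudokinase that targets C/EBP alpha for degradation, at 5.03 ± 0.83, and Pou2af1, a coactivator of POU factors in B cells, at 4.36 ± 0.40. The guides of Trib1 had 422 reads in DMSO and 5696 in SAHA. Its call was lost with the SD taken by the count in the reference library. The transcriptional repressor Bhlhe40 was at 4.21 ± 0.60 and Whsc1l1, the histone methyltransferase now named Nsd3, at 4.20 ± 0.80, each with 5 of 5 guides above 0 and the same adjusted p as Myc.

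The remaining 5 genes with SAHA were Mdm2 at 3.99 ± 1.30 over 4 guides, the forkhead factor Foxp1 at 3.77 ± 0.42 over 5, Ywhaq, a 14-3-3 protein, at 3.69 ± 0.55 over 5, Gch1, the initial enzyme of tetrahydrobiopterin synthesis, at 3.60 ± 0.29 over 4 and Atpif1, the inhibitor of the mitochondrial ATP synthase, at 3.36 ± 1.92 over 4. Their adjusted p-values (guide-set resampling test) ran from 0.0132 for Mdm2 to 0.0475 for Gch1, and 3 of the 4 guides of Atpif1 were above 0. The guides of Mdm2 had 618 reads in DMSO and 7829 in SAHA. Gch1 and Atpif1 fell outside the rule for named genes and were named after their values were seen. On the lower side 505 genes had an unadjusted p under 0.05, on the higher side 614, and chance gives 990 over both sides. The rank-sum of guides also gave 0 genes lower. The test had less reach on that side, where it recovered 22.0% of simulated genes lowered by 4, against 52.0% of those raised by 4. The smallest p on the lower side belonged to Esco2, an acetyltransferase of cohesin, at -6.20 ± 0.67 with 5 of 5 guides below 0 and 9 reads in SAHA against 1732 in DMSO, but it did not pass (adjusted p = 0.277, guide-set resampling test). Olfr911-ps1 at -5.0 ± 1.69 and Xrra1 at -3.63 ± 1.45 followed and did not pass either (adjusted p = 0.309 for each, guide-set resampling test). Guides of Xrra1 and Spcs2 overlapped in position, and Spcs2 was at -1.85 ± 2.16.

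**Figure D3:**
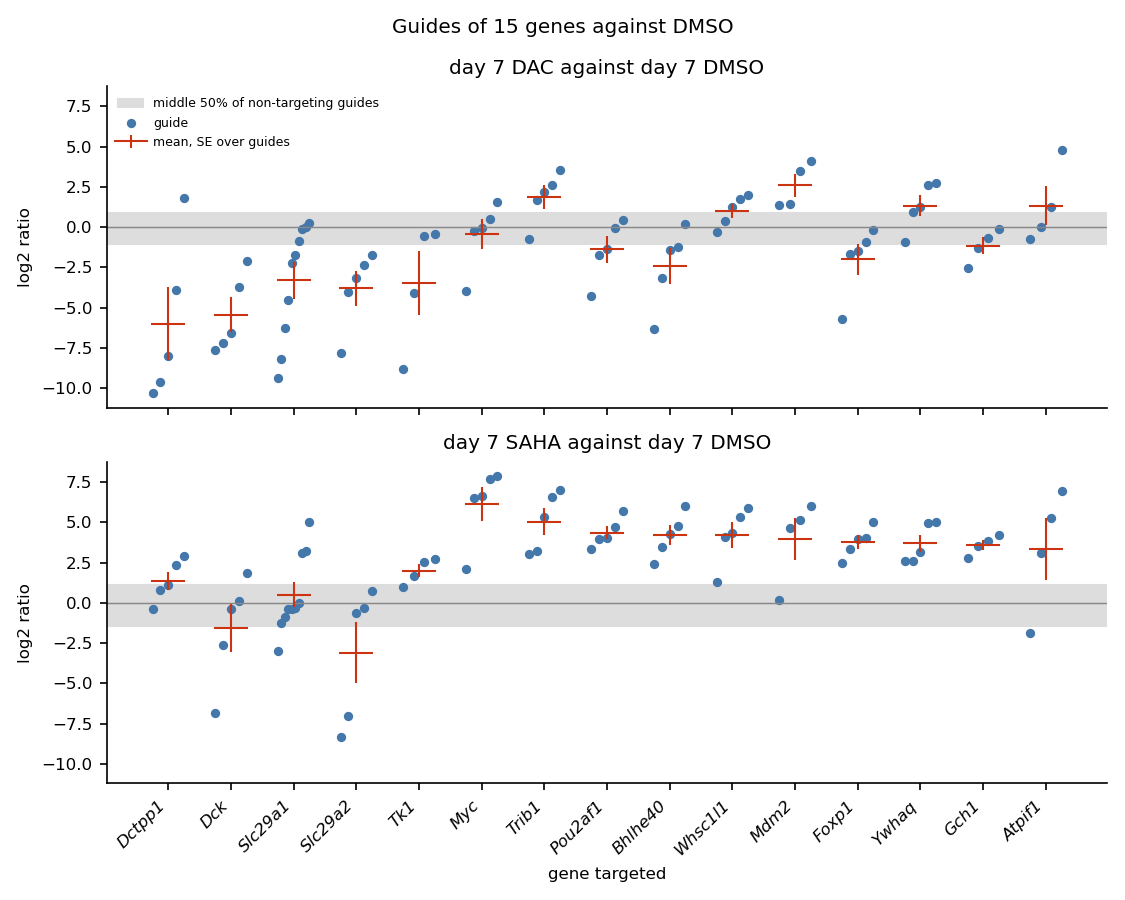
Log2 ratios to DMSO (y axis) of single guides of 15 genes (x axis) with DAC, top, and SAHA, bottom, with the mean and SE over guides as bars and the middle 50% of non-targeting guides as a grey band. With SAHA all 5 guides of Myc lie above 0, and with DAC all 5 guides of Dck lie below 0.

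Zinc-dependent histone deacetylases, the targets of SAHA, showed no passing member among the 9 measured, over all genes or adjusted over the list alone. Hdac2 was at -0.80 ± 1.19 and Hdac3 at -1.57 ± 1.81, each over 5 guides, while Hdac1 and Hdac6 had 2 guides each past the count minimum and were not tested. The drug exporters Abcb1a and Abcb1b were at 0.04 ± 0.57 and -0.65 ± 1.84 and did not pass, and 0 of 12 efflux transporters passed over all genes or over the list alone. Directions turned under other settings, for Abcb1a to -0.41 without its most extreme guide, for Abcb1b to 0.77 with the guide median and for Hdac2 to 1.15 with day 0 as the reference library, and Hdac3 was at 0.00 without its most extreme guide. The value of Hdac2 against day 0 carries the 2 classes of day 0 count.

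Among 12 drivers of the G1 phase 1 passed with SAHA, Myc, and among 17 p53 pathway genes 1 passed, Mdm2, with the same counts when adjusted over the list alone. Of 22 stem cell and leukaemia transcription factors 0 passed over all genes and 1 was higher when adjusted over the list alone, Myb at 3.56 ± 0.73 over 5 guides. Of 25 brakes of RAS and PI3K signalling 0 passed over all genes and 2 were higher when adjusted over the list alone, the RAS GTPase activator Nf1 at 2.90 ± 0.56 and the MAP kinase phosphatase Dusp4 at 2.68 ± 0.74, each over 5 guides. Of 20 myeloid differentiation factors 0 passed over all genes and 1 was higher over the list alone, the repressor Gfi1 at 2.49 ± 0.64 over 5 guides. The median of that list was 0.33, at percentile 100 of random lists with a middle 95% from -1.43 to -0.09. The 17 negative regulators of JAK-STAT signalling had a median of 0.49, also at percentile 100, with 0 members passing over all genes or over the list alone, and their percentile was 83.1 with the guide median.

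Of 31 cytokine receptors, ligands and JAK-STAT genes 0 passed with SAHA over all genes and 1 was lower over the list alone, Flt3l, the ligand of FLT3, at -3.90 ± 1.31 over 7 guides. Guides of Flt3l and Rpl13a overlapped in position, and Rpl13a was at -1.57 ± 1.26. That list's median of -1.29 lay at percentile 2.5. Of 16 cohesin and separase genes 0 passed over all genes. Adjusted over the list alone Esco2 was lower, and Pds5a at 2.38 ± 3.09 over 4 guides and Pds5b at 2.14 ± 0.25 over 5 guides were higher. The mean of Pds5a rested on 1 guide and was -0.71 without it. Sets of 5 non-targeting guides had a mean of -0.51 with a middle 95% from -3.03 to 1.52. With a null drawn from all guides, or with a single SD for all guides, 5 genes passed, with a null drawn from chemosensory receptor guides 16 passed, and with day 0 as the reference library 0 passed, where the values ran from 1.75 for Mdm2 to 7.69 for Myc. The setting with day 0 carries the 2 classes of day 0 count and is another contrast.

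**Figure D4:**
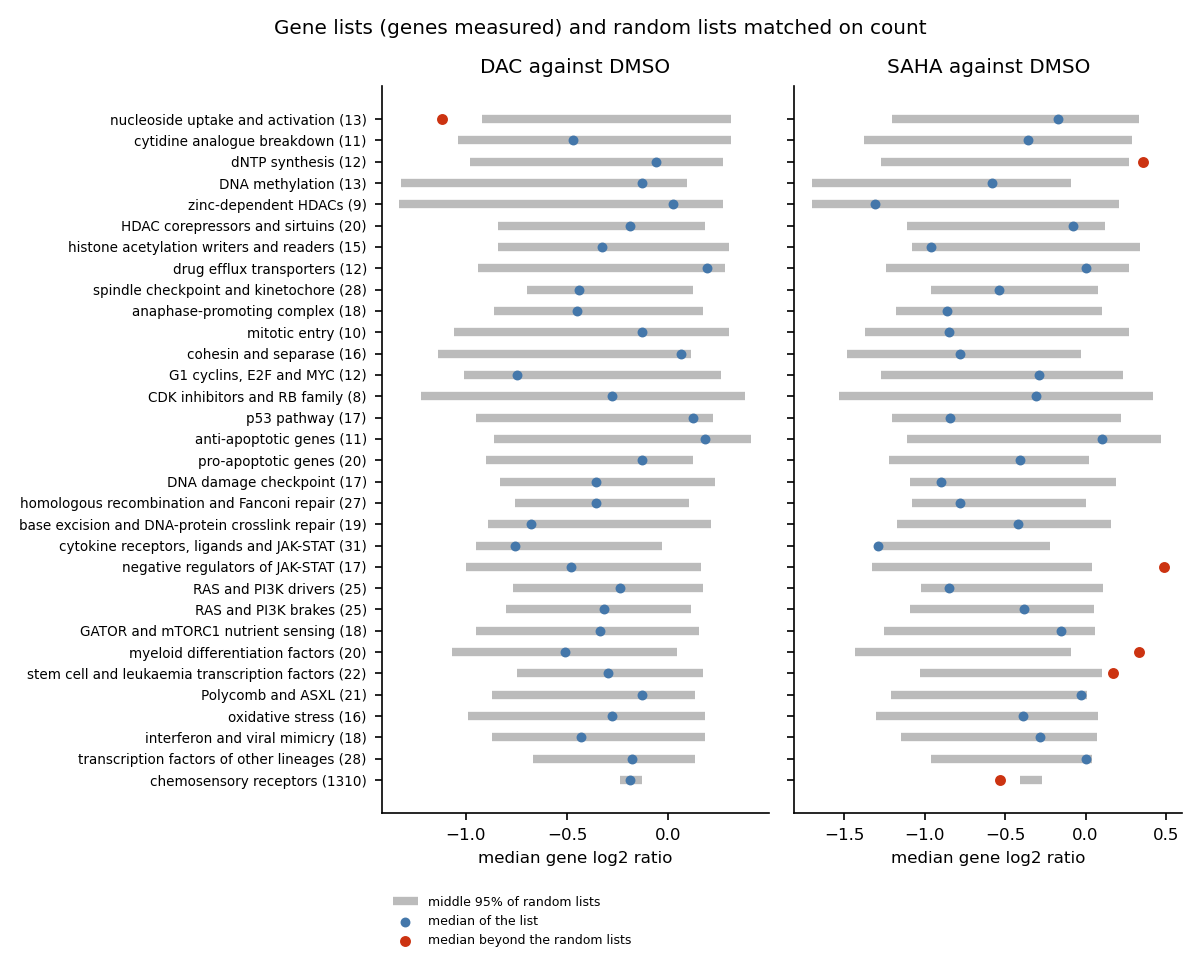
Median log2 ratio of the genes of each list (points, x axis) with the middle 95% of random lists matched on count (grey bars), for 32 lists (y axis, genes measured in parentheses) with DAC, left, and SAHA, right, against DMSO. Nucleoside uptake and activation lies below its random lists with DAC at -1.12, and negative regulators of JAK-STAT lie above theirs with SAHA at 0.49.

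The comparison of day 7 DMSO with day 0 spans the culture with vehicle, but its ratios follow the 2 classes of day 0 count and are not read here as growth. The median scaled count of the high class was 1201.9 at day 0 and 642.0 in DMSO, and that of the low class 20.8 and 346.4. No gene passed in either direction, with 377 genes higher and 772 lower at an unadjusted p under 0.05, against 990 by chance, and the rank-sum of guides gave 0 as well. Among the smallest p on the higher side were Dao, the D-amino-acid oxidase, at 3.33 ± 1.03 and Itsn2 at 2.58 ± 0.34, each with 5 of 5 guides above 0. On the lower side it belonged to Prr14 at -5.75 ± 1.64, Cd5l at -4.55 ± 1.96 and Hr at -5.29 ± 2.14 (adjusted p = 0.524 for each of these genes, guide-set resampling test).

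The mouse genes Setbp1 and Asxl1 did not pass between DMSO and day 0, at -3.07 ± 0.72 over 5 guides and -2.09 ± 1.25 over 4. The guides name the mouse genes, so these values are not read as an effect on the mutants that transformed the cells. Myc was at 0.10 ± 0.99, Trp53 at -1.50 ± 1.91 over 3 guides and Cdkn2a at -1.32 ± 1.83, while Cdkn1a had 0 guides past the count minimum. With scaling by the total count and no centring, the median gene lay 3.20 higher, and the values of Setbp1, Asxl1, Trp53 and Cdkn2a were then above 0. With centring within both classes of day 0 count Trp53 was at 0.89. Adjusted over their lists alone 3 genes were lower, the PI3K brake Inppl1 at -5.20 ± 0.67 over 4 guides, all in the high class at day 0, the nutrient sensor Sesn3 at -5.19 ± 3.22 over 3 and the CDK inhibitor Cdkn1c at -4.66 ± 2.88 over 3, and 0 members of these lists passed over all genes. Sets of 5 non-targeting guides had a mean of -1.08 with a middle 95% from -3.61 to 1.26. When guides were centred and scaled within both classes of day 0 count, an alternative chosen after seeing the data, 1 gene was higher, Dao, and 6 were lower, Gstm2, Nop10, Nrde2, Sema3c, Slit1 and Vamp8.

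The direct comparison of DAC with SAHA tests the difference between the 2 drug libraries without the DMSO library. Guides of 5 genes were lower with DAC than with SAHA and passed the test, with 5 of 5 guides below 0 for each of 4 genes and 4 of 4 for Tk1. These were Dctpp1 at -7.31 ± 1.86, Bhlhe40 at -6.57 ± 1.44 and Myc at -6.54 ± 1.52 (adjusted p = 0.0264 for each, guide-set resampling test), and Pou2af1 at -5.71 ± 1.06 and Tk1 at -5.42 ± 2.22 (adjusted p = 0.0475 for each, guide-set resampling test). Myc guides had 9127 reads in DAC and 292608 in SAHA, and Dctpp1 guides 235 and 3851. No gene passed in the higher direction, where 544 genes had an unadjusted p under 0.05, against 597 lower and 990 by chance over both sides, and the rank-sum of guides gave 0 as well. The smallest p on the higher side belonged to Mob1b at 5.69 ± 1.68, just outside the threshold (adjusted p = 0.0528, guide-set resampling test), the checkpoint adaptor Clspn at 5.15 ± 1.69 and Ogfod3 at 5.48 ± 1.06, each with 5 of 5 guides above 0.

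Within the lists, the nucleoside carriers and kinases had 1 of 13 members lower with DAC than with SAHA over all genes, Tk1, and 2 when adjusted over the list alone, with Slc29a1 at -3.77 ± 1.61 over 10 guides. The call of Tk1 was lost under 16 of 19 alternatives, and its value was -3.39 without its most extreme guide. The nearest guides of Tk1 and Afmid lay 139 bp apart, and Afmid was at 1.55 ± 1.20. Dck was at -3.83 ± 1.71 and did not pass. The list's median of -0.80 lay at percentile 1.7, and at 9.0 with a guide count minimum of 100. Of 25 RAS and PI3K brakes 0 passed over all genes and 2 were lower with DAC over the list alone, Dusp4 at -4.86 ± 1.78 and Nf1 at -3.73 ± 0.50. Of 17 negative regulators of JAK-STAT 0 passed over all genes and 2 were lower over the list alone, Socs1 at -6.35 ± 0.46 over 3 guides and Ptpn1 at -4.54 ± 1.81 over 5. Esco2 at 6.34 ± 0.84 and the mitotic kinase Cdk1 at 6.24 ± 1.86 over 3 guides were higher with DAC over their lists alone and did not pass over all genes. Hdac2 at -1.43 ± 1.55, Hdac3 at 1.63 ± 1.56, Dnmt1 at 2.42 ± 1.69 and Samhd1 at 2.77 ± 1.11 did not pass. Sets of 5 non-targeting guides had a mean of 0.19 with a middle 95% from -2.49 to 2.87. The 5 calls were all lost with a single SD for all guides and with the mean of the 3 guides farthest from 0, and 4 of them were lost with the SD taken by the count in the reference library. Scaling by edgeR's TMM gave 1 gene higher, Mob1b, and 4 lower, and scaling by DESeq2's size factors gave 1 higher and 10 lower.

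Across 19802 genes the ratios of DAC to DMSO and of SAHA to DMSO had a Pearson correlation of 0.22 (bootstrap 95% interval 0.21 to 0.24) and a Spearman correlation of 0.22. Genes are not independent replicates, and both ratios share the DMSO library. Sets of 5 non-targeting guides, which target nothing, gave 0.21 and 0.20. The covariance was 0.286 over genes and 0.237 over the non-targeting sets, a difference of 0.05. At an unadjusted p under 0.05, 62 genes were higher with both drugs and 31 lower with both, against 15.2 and 12.9 for independent lists and 42.9 and 30.1 for non-targeting sets that share the DMSO library. With 1 DMSO library the controls could not be split.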

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

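In this part, the tests for a gain or a loss with either drug, the test for an outgrowing guide in Mdm2 and in Atpif1, the reading of the null from all guides for 5 genes, and the tests by calls in simulated libraries were chosen only after the result was seen. The 5 genes below were picked out because a direct test of the DAC library against the SAHA library passed for them. Dctpp1 differed by -7.31 ± 1.86, with -6.00 ± 2.25 for DAC and 1.36 ± 0.58 for SAHA, each against DMSO. Bhlhe40 differed by -6.57 ± 1.44, with -2.40 ± 1.12 for DAC and 4.21 ± 0.60 for SAHA. Myc differed by -6.54 ± 1.52, with -0.42 ± 0.94 for DAC and 6.16 ± 1.05 for SAHA. Pou2af1 differed by -5.71 ± 1.06, with -1.39 ± 0.82 for DAC and 4.36 ± 0.40 for SAHA. Tk1 differed by -5.42 ± 2.22 over 4 guides, with -3.47 ± 1.98 for DAC and 1.99 ± 0.40 for SAHA. The difference of Tk1 was past the threshold in 3 of 19 alternatives only, and its size was -3.39 without its most extreme guide.

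Guides of 10 genes were higher with SAHA than with DMSO. An outgrowing guide in each gene does not go with the table, because 8 of the 10 still passed without their most extreme guide, which just meets the bound of 8 set beforehand. For Mdm2 and Atpif1 it cannot be told apart from an effect of the gene, since 0 of the 2 passed without that guide, at 3.32 with an unadjusted p of 4.6e-05 and at 2.16 with 0.00144 in the resampling test. Non-targeting guides that vary less than targeting guides had an SD of 2.62 against 2.67, and are argued against for Myc, Trib1, Pou2af1, Bhlhe40 and Whsc1l1, the 5 of the 10 that passed over all genes with the null from all guides, while this stays open for the other 5. The null from chemosensory receptor guides, with 10 of 10 passing, decides nothing, since these receptors had a median of -0.53 with SAHA, below random lists, and that null gave 1064 genes higher and 384 lower at an unadjusted p under 0.05.

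For Myc, Bhlhe40 and Pou2af1, the 3 of the 10 that passed over all genes in the direct comparison, the DAC and SAHA libraries differed. Their call there was lost under some alternatives. The direct comparison uses again the SAHA library by which the 10 genes were picked. It does not tell a drug effect from a change private to that 1 culture, so a like gain with either drug is not excluded. A like gain also stays open for the other 7 genes. With DAC these were Mdm2 at 2.59 ± 0.71, Trib1 at 1.86 ± 0.72, Atpif1 at 1.33 ± 1.22, Ywhaq at 1.32 ± 0.66, Whsc1l1 at 1.02 ± 0.43, Gch1 at -1.16 ± 0.52 and Foxp1 at -1.99 ± 0.96, and Mdm2 was at -0.07 with day 0 as the reference library. That last value carries the 2 classes of day 0 count. The median of a gain with either drug over the 10, 0.30 (random sets -0.50 to 0.57), decides nothing, since 5 genes lay above 0 and 5 below. Chance calls among many genes stay open for part of the 10. The simulated libraries do not give their number. For SAHA against DMSO 5 unchanged genes were called there, beside 26 recovered genes raised by 4 and 11 lowered by 4. With more genes passing there than here, a larger unadjusted p passes the adjusted threshold. Those 5 therefore cannot be set against the 10.

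Guides of Dctpp1 and of nucleoside carriers and kinases were lower with DAC than with DMSO. An outlying guide in each gene does not go with the table, because 5 of the 5 genes kept an unadjusted p under 0.05 on the lower side without their most extreme guide, at -4.92 for Dctpp1, -4.90 for Dck, -2.64 for Slc29a1, -2.82 for Slc29a2 and -1.69 for Tk1. Chance among many genes is not excluded for the carriers and kinases. Of 10000 random lists 1, or 0.01%, had as many members on the lower side as the 4 observed. But the list was weighed because of those same members, and that share does not allow for the 4 comparisons and both directions. The list's median lay at percentile 14.2 with a guide count minimum of 100 and 13.8 with the guide median. Between DMSO and day 0, with the same DMSO library, it lay at percentile 97.9, on the higher side. That list does not hold Dctpp1, for which chance calls among many genes stay open. The simulated libraries do not settle it. For DAC against DMSO 4 unchanged genes were called there, beside 37 recovered genes raised by 4 and 13 lowered by 4. With so many recovered genes a larger unadjusted p passes the adjusted threshold. Those 4 therefore cannot be set against the 1 gene called here. For Dctpp1 and Tk1, the 2 of the 5 that passed over all genes in the direct comparison, the DAC and SAHA libraries differed. This holds less firmly for Tk1, whose call there was lost under 16 alternatives. The direct comparison uses again the DAC library by which the 5 genes were picked. It does not tell a drug effect from a change private to that 1 culture, so a like loss with either drug is not excluded. A like loss also stays open for Slc29a1, Dck and Slc29a2, at 0.51 ± 0.78 with 3 of 10 guides above 0, -1.58 ± 1.5 and -3.09 ± 1.89 with SAHA. In the direct comparison they were at -3.77 ± 1.61, -3.83 ± 1.71 and -0.68 ± 1.55. The list's percentiles of 72.2 with SAHA and 1.7 in the direct comparison do not settle it. Of the list's genes named here, Slc29a1 and Tk1 lay above 0 with SAHA, and Dck and Slc29a2 below.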

How the results depend on the processing

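In this part, the SD by the count in the reference library, the guide count minimum on the 2 compared libraries, that on the day 7 libraries, and the centring within 2 classes of day 0 count were chosen after seeing the data, as was the count of list medians beyond random lists. No paired analysis was possible because each group had 1 library, and every replicate number was 1. The count of genes higher with DAC than with DMSO and that of genes lower with SAHA than with DMSO were 0 under each of 20 alternatives. Dctpp1 was the 1 gene lower with DAC under 17 of 20, and 0 genes were lower with the rank-sum of guides, with a single SD for all guides and with day 0 as the reference library. The count of 10 genes higher with SAHA ran from 7 to 10 under 16 of 20. It was 5 with the null from all guides and 5 with a single SD, with 5 of the 10 kept each time, 16 with the null from chemosensory receptor guides, with 10 of the 10 kept, and 0 with day 0 as the reference library. For both drugs the setting with day 0 carries the 2 classes of day 0 count and spans the culture too, so it is another contrast. Among the 10, Gch1 lost its call under 14 alternatives and Atpif1 under 10, and Myc, Pou2af1 and Bhlhe40 under 1. With the SD by the count in the reference library the calls of Trib1, Mdm2 and Atpif1 were lost.

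Between DMSO and day 0 the count of genes higher was 0 except for 1 with DESeq2's size factors, Dao, 1 with each promoter apart, Dusp14, and 1 with centring within classes of day 0 count, Dao. The count of genes lower was 0 except for 6 with that centring. Between DAC and SAHA the count of genes higher was 0 except for 1, Mob1b, with TMM, with DESeq2's size factors, with the null from all guides and that from chemosensory receptor guides, with each promoter apart and with the minimum on the day 7 libraries. The count of 5 genes lower ran from 4 to 6 under 10 of 19. It was 3 with a pseudocount of 0.5, with a guide count minimum of 100, with the total count and no centring and with the null from all guides. It was 10 with DESeq2's size factors, 11 with the null from chemosensory receptor guides, 1 with the SD by the reference library, and 0 with a single SD and with the mean of the 3 guides farthest from 0. Tk1 lost its call under 16 alternatives and Pou2af1 under 8. The correlation of the drug ratios was 0.13 with a guide count minimum of 100, where non-targeting sets gave 0.14, and 0.54 over the 11 genes that passed with either drug, with a bootstrap interval from -0.31 to 0.89 and a Spearman correlation of 0.16, for genes chosen by the ratios themselves, against 0.21 for non-targeting sets. For each of these changes the cause was not tested.

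Of 128 list medians 16 lay beyond the middle 95% of random lists, where chance gives 6.4, and 12 to 16 did under 6 alternatives. With a guide count minimum of 100, 7 of the 16 were kept, and with the guide median 8. Scaling moved the median gene between DMSO and day 0 by 3.20 with the total count, 2.38 with TMM, 0.98 with DESeq2's size factors and 0.37 with centring on all guides. It moved it for SAHA against DMSO by -1.21, -0.23, -0.06 and 0.11, for DAC against DMSO by -0.43, -0.09, 0.02 and 0.00, and for DAC against SAHA by 0.75, 0.11, 0.06 and -0.04. No gene past the threshold changed direction under any alternative, while genes that did not pass changed sign under some.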

Other observations

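In this part, all 3 tests of the day 0 classes were chosen only after the result was seen. In the direct comparison 2 enzymes of dNTP synthesis were lower with DAC than with SAHA when adjusted over their list alone, Ctps2 at -5.17 ± 3.05 over 3 guides and Tyms at -4.00 ± 0.76 over 5 guides, and neither passed over all genes. With SAHA against DMSO the median of the dNTP synthesis list was 0.36, at percentile 98.5 of random lists, and 97.4 with a guide count minimum of 100, with 0 of 12 members passing over all genes or over the list alone. In the base excision and crosslink repair list 2 members were lower with DAC than with SAHA over the list alone, Topors at -3.76 ± 2.52 over 4 guides and Xrcc1 at -3.15 ± 1.74 over 5 guides, and neither passed over all genes. In the same list 1 member, not named here, was higher over the list alone. The list's median of -0.10 lay at percentile 26.2 of random lists, so the list did not move in 1 direction. The genes named in this paragraph were chosen after their values were seen.

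Among other lists, the 17 p53 pathway genes lay at percentile 93.3 with DAC against DMSO and from 74.0, with no guide count minimum, to 100, with the guide median, under the alternatives. In the direct comparison their median of 1.06 lay at percentile 98.8, and at 97.4, 91.1 and 95.9 under 3 alternatives. That of 16 cohesin and separase genes, 1.17, lay at percentile 98.5, and at 94.6, 92.2, 83.2 and 74.6 under 4 alternatives. Between DMSO and day 0 the myeloid differentiation factors lay at percentile 0.3, the RAS and PI3K brakes at 0.7 and the G1 drivers at 1.8, with 0 genes passing in each. With a guide count minimum of 100 these were 5.9, 7.4 and 5.4, and with the guide median the brakes lay at 17 and the G1 drivers at 12.7. The 1310 chemosensory receptor genes, listed as genes of other tissues, had a median of -0.53 with SAHA against DMSO, below the random range from -0.41 to -0.27, and 0 of them passed over all genes. They lay at percentile 38.9 with DAC against DMSO and, on the other side, at -1.20 above the random range from -1.46 to -1.30 between DMSO and day 0. With no matching on count the percentile was 7.1 with SAHA, 99.1 with DAC and 90.6 between DMSO and day 0.

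Of 105548 guides with a read in DMSO, 9340 had 0 reads in DAC and 14024 in SAHA. Among non-targeting guides in the lowest of 4 groups of DMSO count 25.6% were at 0 in DAC and 38.6% in SAHA, and in the highest group 0.5% and 0.9%. Targeting guides gave 28.6% and 37.8% in the lowest group, and 0.2% and 0.5% in the highest.

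The day 0 library had 2 classes of guide count, split here at 200 reads, with medians of 1500 and 26 reads, a ratio of 57.69. Guides of low day 0 count being rare in the cells does not go with the table, because the ratio of the same classes was 1.85 in DMSO, 2.40 in DAC and 2.73 in SAHA, under the bound of 5. Selection on the targeted genes is argued against by the shares of high class guides, which differed by 0.6 percentage points between targeting and non-targeting guides. Pools of whole genes amplified unevenly are argued against too, since 10.7% of genes with 5 guides had all 5 in 1 class, where 9.6% would if guides fell independently. What made the classes stays open, and no biological explanation beyond selection was tested.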
